A study of Homo sapiens with 3 samples.

How the data were processed

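The samples were 3 specimens of prostate transition zone, digested with collagenase for 4 h, sorted for viable cells and loaded on a droplet platform (10x Genomics 3' chemistry, about 17400 cells loaded per the labels), with 1 library each. The deposited values are counts of UMIs per gene and barcode, made with Cell Ranger 3.1.0 on genome build GRCh38 per the submitters' processing notes, with cell barcodes already called. The annotation release, the sequencer used for each sample and the handling of reads that match several genes are not given in the sources used here. Printed gene positions were taken from GENCODE v29. All 3 specimens carry the same description and form 1 group, so no condition was compared, and specimens are called replicates 1 to 3 in the order of the series. The labels do not state that the specimens came from different patients, so p-values refer to these samples and not to patients. They measure how class differences varied between the samples after the specimen term, pooled over the classes. The 3 libraries were checked to be distinct: they shared 86, 78 and 123 barcodes in pairs, and their summed counts differed by a chi-square per degree of freedom of 252, 150 and 176.

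Of 33538 genes in the files, 775 were left out everywhere: sex-specific genes, immunoglobulin and T cell receptor segments, and genes whose presence varies by inherited deletion or haplotype. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 5208, 7251 and 8113. Doublets were scored with the Scrublet method in scanpy 1.11.5. Its own threshold called 1, 1 and 3 cells, so the highest-scoring share expected from loading, 0.8% per 1000 barcodes, was removed instead: 251, 534 and 636 cells. The 19151 kept cells had medians of 1472, 1763 and 1431 genes in replicates 1, 2 and 3. Each specimen was clustered alone: counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, chosen without list, mitochondrial and ribosomal genes, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1.0 (igraph 0.11.9).

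The 54 clusters were named from 18 marker sets. A cluster's score was the mean of its markers' log levels, scaled from 0 to 1, over markers of at least 50 CPM in some cluster. The scaling ran across the 54 clusters of all specimens together, so names were not given in each specimen alone. A name needed a score of at least 0.5 and a gap of 0.1 to the next, or, in a near tie, at least 2 markers among the 10 leading genes. Clusters whose leading genes held more markers of another class stayed unnamed, which together with the other conditions left 5 without a name. The rule gave 11 classes, called "-like" because expression alone defines them, with at least 20 cells in each of 33 pseudobulks. Their summed UMIs ran from 212281 in mast-like to 24665741 in basal-like cells. Naming markers were not counted in the gene lists. Shares have exact Clopper-Pearson 95% intervals, and these intervals, like the floor of 3 counts, cover counting error only.

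Pseudobulks of all 11 classes were fitted together in edgeR 4.0.16 with TMM scaling, its filter on low counts, terms for class and specimen, and the quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method over the 11630 genes tested. An adjusted p under 0.05 counted as passing. Standard errors (SE) were back-calculated as the absolute log2 fold change over the square root of the test's F statistic. They are not standard errors of the fitted coefficient. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes and adjusted over the 12 lists of a comparison, and again with the correlation estimated. Counts "adjusted over the list alone" repeat the adjustment within the members. Fold changes of genes with 0 counts in a class are given as bounds at 3 counts over the class, and those with 1 to 3 counts as ratios with counting intervals. List medians are also given with such genes at their bound where this differs. Drug target levels are plain CPM, and levels in the comparisons are CPM after TMM scaling.

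Named genes followed a rule. From each list, up to 2 genes with the largest absolute log2 fold change were named among those that passed, moved the same way in every specimen and reached 20 CPM in the higher class. Outside the lists, the 3 most positive and 3 most negative genes were named under the same conditions at 100 CPM, leaving out markers and genes used for clustering. All 10 drug targets were named, with 3 steroid receptors. Some results that the rule selects are left out of the text and the plots. The comparisons, lists, marker sets, naming rule for genes, filters and 95 alternatives were chosen before the data were examined. After the data were seen, 3 alternatives were added: leaving out clusters led by stress genes, giving unnamed clusters their first class, and scaling by library size alone.

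The procedure was tested on simulated data with 100 genes changed by 1 and 100 by 2 log2 units per comparison. At 1 unit it called 19%, 22%, 25%, 7%, 13% and 17% of the changed genes, in the order of the report, and at 2 units 82%, 81%, 80%, 63%, 64% and 61%, all with the right sign. False calls were 4 of 105, 3 of 106, 4 of 109, 3 of 73, 2 of 79 and 5 of 83. Of 11 lists without a shift camera called 0, and it called the 1 list with a shift. The simulated genes were drawn independently, so this could not show false list calls that arise from correlation between genes. Their spread followed the trend over all genes, and as many changed genes went up as down. False calls from scaling, from genes with a spread of their own or from classes formed on the same cells could therefore not show either. The pairing of classes by specimen was checked over 7305 genes: deviations from the class mean correlated at 0.25 to 0.57 within a specimen and at -0.40 to 0.11 between specimens. These correlations are across genes, which are not independent replicates, and centring on 3 specimens pulls the values between specimens below 0. Alternatives covered scaling, the low-count filter, DESeq2 1.42.0, the specimen term, a fit of the 2 classes alone, doublets, the mitochondrial limit, cell minimums, resolution, joint clustering, subtraction of free RNA, fry, and leaving out each replicate. Analyses ran in R 4.3.3 and Python 3.11.15, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.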

Results

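Viable cells sorted from the transition zone of the human prostate, the region that enlarges in benign prostatic hyperplasia (BPH), were profiled by droplet single-cell RNA sequencing in 3 specimens that form 1 group. The labels call the tissue normal in one field and diseased, from patients with BPH, in others, so no statement on health or disease is drawn here. The deposited matrices held 6015, 9209 and 9799 barcodes and 27973072, 52489226 and 49262569 unique molecular identifiers (UMIs) in replicates 1, 2 and 3. After filtering, 4957, 6717 and 7477 cells were kept, with medians of 4732, 6296 and 5118 UMIs per cell. With 1 group, the comparisons were made between cell classes of the same specimens: which genes set apart the epithelial, stromal and leukocyte classes of this tissue, and which classes held the targets of BPH drugs.

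Cells of named epithelial classes made up 57.9% ± 9.76 of the kept cells (SD, n = 3), those of named stromal and endothelial classes 10.7% ± 4.95 and those of named leukocyte classes 22.3% ± 7.27. Basal-like cells, which carry keratins 5, 14 and 15, were the most frequent class at 38.5% ± 12.1. Club-like cells, named from a set with secretoglobins and PIGR, made up 8.27% ± 3.56, and hillock-like cells, named from a set with KRT13 and KRT4, 4.43% ± 2.90. Not every cluster was led by these genes. A club-like cluster of 760 cells in replicate 3 had MMP7 as its 1 leading club marker. SERPINB3 and LY6D led the hillock-like cluster of each replicate, KRT13 those of replicates 1 and 3, KRT4 none, and the secretoglobin SCGB1A1 those of replicates 1 and 2. Luminal secretory-like cells, which carry KLK3 and MSMB and are called luminal-like from here on, averaged 6.69% ± 7.98. Their share was 2.58% in replicate 1 (exact Clopper-Pearson 95% interval 2.16 to 3.06), 1.61% in replicate 2 (1.32 to 1.94) and 15.9% in replicate 3 (15.1 to 16.7). In replicate 3, 675 of these cells came from a cluster led by MT1G. It scored 0.722 for luminal markers but had 0 of them among its 10 leading genes. Mural-like cells, named from smooth muscle or pericyte markers, made up 5.53% ± 1.07, blood endothelial-like cells 3.16% ± 2.71 and fibroblast-like cells 2.01% ± 1.24. Among leukocytes, T/NK-like cells made up 8.87% ± 2.24, myeloid-like cells 7.53% ± 4.34, mast-like cells 3.01% ± 1.98 and B/plasma-like cells 2.88% ± 1.53. Clusters that could not be named held 15%, 12.3% and 0% of the cells of replicates 1, 2 and 3, where a count of 0 allows up to 0.0401%. Most of these cells scored highest for epithelial markers: 556 in replicate 1 for basal, and in replicate 2 682 for club and 146 for basal. The epithelial mean and its spread therefore depend on the naming rule. The hillock-like share averaged 1.48% with a mitochondrial limit of 20%, 1.84% at resolution 0.6 and 2.12% with the specimens clustered together. Without replicate 3 the mean shares of luminal-like, hillock-like, blood endothelial-like and fibroblast-like cells were 2.10%, 2.75%, 1.60% and 1.32%, and that of mast-like cells was 1.98% without replicate 1.

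**Figure D1:**
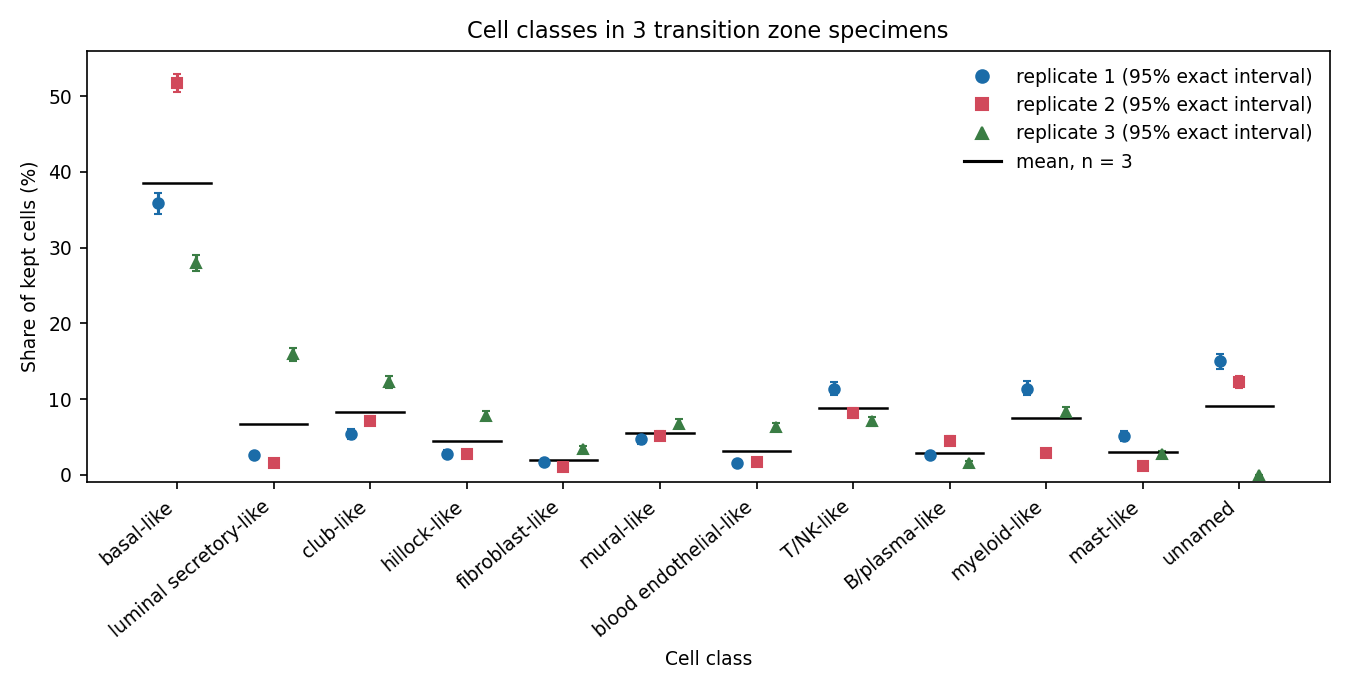
Share of kept cells (%) in each of 11 named classes and in unnamed clusters; symbols are the 3 specimens with exact 95% intervals, which cover counting error only, and bars are means. Basal-like cells ranged from 28.0% to 51.7%, and luminal-like cells from 1.61% to 15.9%.

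Transcripts of other classes were counted in T/NK-like cells, and these values do not separate free RNA from remaining doublets or misplaced cells. KLK3, made by luminal cells, averaged 102 ± 82.2 counts scaled to 1000000 per pseudobulk (CPM, SD, n = 3) in T/NK-like cells against 13000 ± 4340 in luminal-like cells. KRT5 averaged 29.9 ± 23.6 CPM in T/NK-like cells against 526 ± 164 in basal-like cells. DCN, a fibroblast proteoglycan, averaged 3.80 ± 2.89 CPM in T/NK-like cells against 3650 ± 91.3 in fibroblast-like cells.

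Of the targets of the 5-alpha-reductase inhibitors, SRD5A2 averaged highest in fibroblast-like and SRD5A1 in hillock-like cells. SRD5A2 (ENSG00000277893), the main prostatic 5-alpha-reductase, averaged 64.6 ± 54.1 CPM in fibroblast-like cells (SD, n = 3), at most 2.14 ± 1.98 in any other class, and had 0 counts in mural-like cells, which allows up to 0.735 CPM. It lies on chromosome 2 from 31522480 to 31581067 in GRCh38. SRD5A1 was counted in all 11 classes and averaged 17.8 ± 12.8 CPM in hillock-like cells. PDE5A, the phosphodiesterase blocked by tadalafil, averaged 39.2 ± 25.1 CPM in mural-like and 34.2 ± 13.4 CPM in fibroblast-like cells, and at most 1.57 ± 1.38 CPM in any other class. CHRM1, a muscarinic receptor, averaged 29.1 ± 23.1 CPM in luminal-like cells, and CHRM3, the receptor that contracts bladder muscle, 5.81 ± 5.05 CPM in fibroblast-like cells. The alpha-1 adrenoceptor genes ADRA1A and ADRA1B had 0 counts in all 11 classes. The 0 counts allow up to 0.735 CPM in mural-like and 1.39 CPM in fibroblast-like cells, so these receptors were not detectable at this depth in the cells sampled. Every mural-like cluster had the pericyte marker RGS5 among its leading genes. The best score was for smooth muscle in replicate 1, for pericytes in replicate 2 and for either in replicate 3. The values therefore do not settle whether the smooth muscle of the stroma expresses these receptors. ADRA1D had 3 counts in all, CHRM2 had 2 and ADRB3 had 7. Among steroid receptors, PGR, the progesterone receptor, averaged 26.6 ± 15.4 CPM in fibroblast-like and 11.5 ± 5.49 in mural-like cells, and ESR1, estrogen receptor alpha, averaged highest in mural-like cells at 4.32 ± 1.84. NR3C1, the glucocorticoid receptor, averaged 284 ± 88.6 CPM in T/NK-like cells. Without replicate 1 the means in these classes were 33.8 CPM for SRD5A2, 10.7 for SRD5A1, 24.7 for PDE5A in mural-like cells and 17.7 for CHRM1, and without replicate 2 that of CHRM3 was 8.72.

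**Figure D2:**
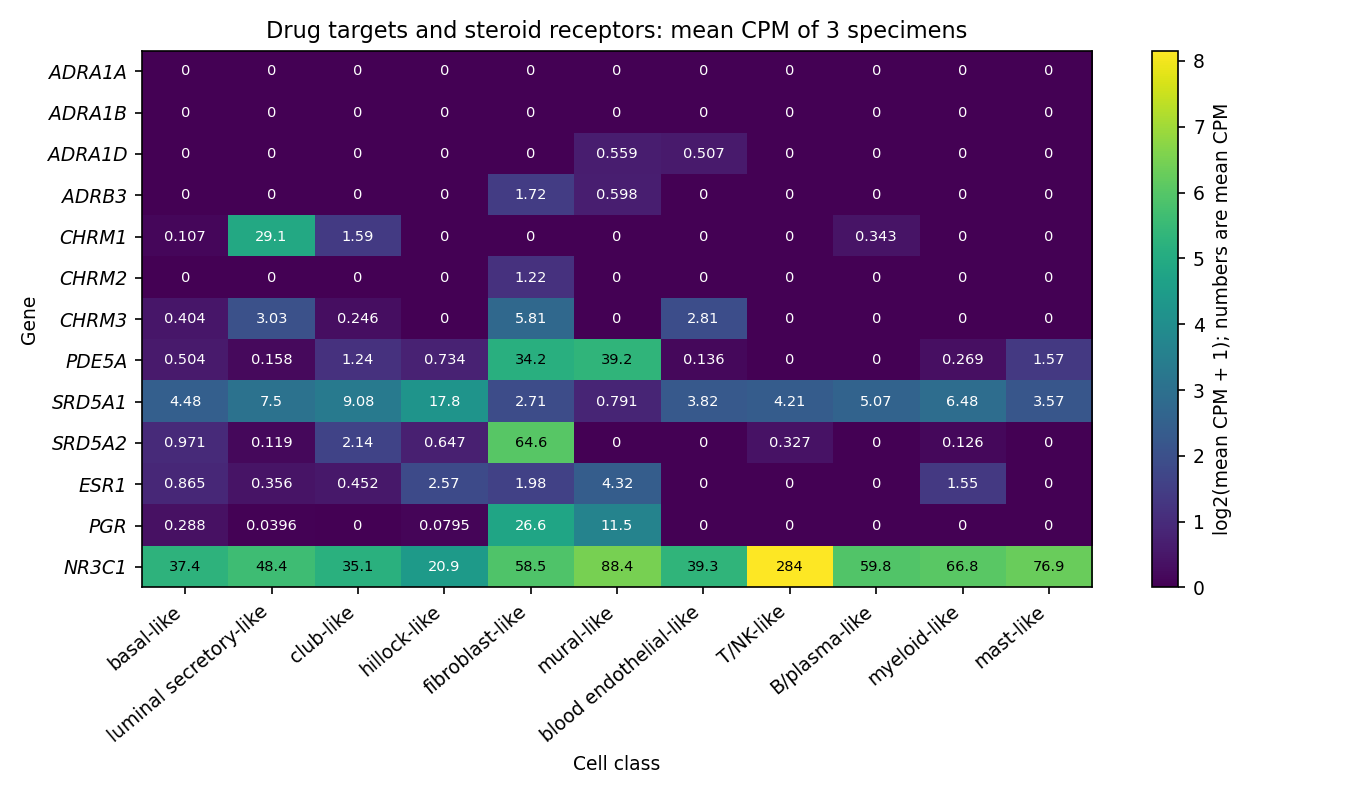
Mean CPM (n = 3 specimens) of 10 drug target genes and 3 steroid receptor genes in 11 cell classes; colour is log2(mean CPM + 1) and the printed numbers are mean CPM. SRD5A2 reached 64.6 CPM in fibroblast-like cells and PDE5A 39.2 CPM in mural-like cells, while ADRA1A and ADRA1B had no counts.

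Genes were grouped by 12 lists chosen before the data were examined, and each of 6 class comparisons was read first by these lists and then by single genes. Because the classes were formed from the expression of the same cells, the p-values describe differences between groups made to differ, measured against the spread between these 3 samples. Of the 72 list results, 39 had a camera adjusted p under 0.05 with the preset correlation, and 12 of these also with an estimated correlation. The BPH drug target list, with 3 of its 10 members tested, was called only in fibroblast-like against basal-like cells, and in the remaining epithelial and leukocyte comparisons camera gave adjusted p = 0.64, 0.11, 0.79 and 0.86. In club-like against luminal-like cells it was called in 2 of 16 alternatives. Among the alternatives counted here and below, fry tests a list for a change and not against other genes, and it gained 8 calls and lost 2. The median, mean and test of a list differed in sign among called results only for antigen presentation in leukocytes. Among results not called they differed for antigen presentation in luminal-like and in fibroblast-like against basal-like cells, for fibrillar matrix in club-like cells, for chemokines between the stromal classes, for androgen response in fibroblast-like against basal-like and in myeloid-like cells, and for immediate early genes in myeloid-like cells. Metallothionein, HLA class II, SAA, HSP70 and KRT6 genes have near-identical relatives, and how reads matching several genes were counted is not given in the sources used here, so the split among relatives is uncertain. Against the scaling used, RLE size factors moved the median of all genes by 0.19, -0.12 and 0.22 (log2) in luminal-like against basal-like, club-like against luminal-like and fibroblast-like against basal-like cells. Library size alone moved it by 0.39 in both comparisons with basal-like cells, by 0.26 between the stromal classes and by -0.13 in leukocytes.

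Between luminal-like and basal-like cells, the secretory and the anchoring layers of the gland, the androgen response list was called higher in luminal-like cells, the 1 list whose call held with an estimated correlation (adjusted p = 0.0027). SLC45A3 (ENSG00000158715), the transporter-like prostein, averaged 283 ± 196 normalised CPM in luminal-like and 1.62 ± 1.70 in basal-like cells (SD, n = 3). It lies on chromosome 1 from 205657851 to 205680459. LAMB3, a laminin chain, averaged 12.6 ± 8.06 CPM in luminal-like and 253 ± 60.5 in basal-like cells. MT1G, a zinc-binding metallothionein, averaged 1969 ± 1087 CPM in luminal-like and 57.3 ± 35.7 in basal-like cells. Without replicate 1, SLC45A3 averaged 170 and 0.658 CPM, and without replicate 3, MT1G averaged 36.7 in basal-like cells. Each gene named for this comparison passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and moved the same way in 3 of 3 specimens, with adjusted p of at most 0.0196.

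The androgen response list had 22 of 26 members higher and none lower in luminal-like cells (22 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 3.57 and a camera adjusted p = 2.7e-14. TMEFF2, a membrane protein with follistatin domains, was higher by 8.28 ± 0.84 (log2, SE). The citrate, zinc and polyamine list had 11 of 27 members higher and 3 lower (12 and 3 adjusted over the list alone; median 0.63, camera adjusted p = 6.2e-04), with adjusted p = 0.053 with an estimated correlation. SLC30A4, a zinc transporter, was higher by 5.36 ± 0.45. Of the basement membrane and hemidesmosome list, 20 of 27 members were lower and 2 higher, the same counts adjusted over the list alone (median -2.16, camera adjusted p = 4.7e-06, adjusted p = 0.062 with an estimated correlation). COL17A1, the hemidesmosomal collagen, differed by -3.97 ± 0.56. Growth factors and morphogens had 23 of 46 members lower and 3 higher, again the same adjusted over the list alone (median -1.45, camera adjusted p = 6.0e-05, adjusted p = 0.053 with an estimated correlation). NRG1, a ligand of ERBB receptors, differed by -5.33 ± 0.61, whereas IGFBP5, a binder of insulin-like growth factors, was higher by 6.02 ± 0.86. Fibrillar and elastic matrix genes had 12 of 28 members lower and none higher, also adjusted over the list alone (median -1.59, or -1.23 with members without counts at their bound, camera adjusted p = 0.0018, adjusted p = 0.11 with an estimated correlation), among them TIMP3, a metalloproteinase inhibitor, at -4.53 ± 0.52, and MMP2, a gelatinase, at -5.16 ± 0.70.

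Keratins and squamous envelope genes had 9 of 20 members lower and 3 higher in luminal-like cells, as adjusted over the list alone (median -0.97, camera adjusted p = 0.0022, adjusted p = 0.11 with an estimated correlation). S100A2, a calcium-binding protein, differed by -4.67 ± 0.43 and the envelope protein CSTA by -4.51 ± 0.51. Immediate early and heat shock genes had 15 of 26 members higher and 3 lower (16 and 3 adjusted over the list alone; median 1.29, camera adjusted p = 2.8e-04, adjusted p = 0.33 with an estimated correlation). HSPA6, an inducible HSP70 gene, was higher by 3.46 ± 0.91, a call lost without the specimen block (2.16, edgeR adjusted p = 0.17), and MYC differed by -3.40 ± 0.43. Clusters led by such stress genes held 251 basal-like cells of replicate 1 and 404 luminal-like cells of replicate 3. No call was made for chemokines and cytokines (3 higher and 11 lower of 39; 2 and 10 adjusted over the list alone, camera adjusted p = 0.066), although CXCL6, which attracts neutrophils, differed by -4.16 ± 0.47 and CCL2, which attracts monocytes, by -3.36 ± 0.55. Nor was one made for mucosal defence (5 higher and 4 lower of 24, as over the list alone, adjusted p = 0.77), antigen presentation (2 and 5 of 23, as over the list alone, adjusted p = 0.94) or steroid receptors and enzymes (3 and 1 of 15, or 3 and 0 over the list alone, adjusted p = 0.31, called in 1 of 17 alternatives). SAA1, an acute-phase protein, differed by -4.53 ± 0.36, TFF1, a trefoil peptide, by 3.95 ± 0.51, SULT2B1, a sterol sulfotransferase, by 2.98 ± 0.34, and the class II chain HLA-DPB1 by 1.06 ± 0.37. CD74, the class II invariant chain, differed by -1.04 ± 0.35 (edgeR adjusted p = 0.0173, lower in 3 of 3 specimens), a call lost in 8 of 17 alternatives. Without replicate 2, neither CD74 (-0.53, edgeR adjusted p = 0.284) nor HLA-DPB1 (0.49, adjusted p = 0.242) passed. The chemokine list was called lower in 9 of 17 alternatives, among them without replicate 2 (camera adjusted p = 0.0411) and without replicate 3 (adjusted p = 0.00462), where its mean log2 fold change was -1.72 against -0.66. Outside the lists, the choline transporter-like gene SLC44A4 (5.43 ± 0.34), the fatty acid desaturase SCD (4.71 ± 0.45) and RAB27B, of vesicle secretion (3.99 ± 0.37), were highest. Caveolin CAV1 (-4.93 ± 0.43), the noncoding RNA MEG3 (-4.92 ± 0.47) and the urea transporter SLC14A1 (-4.88 ± 0.43) were lowest.

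In all, 2344 genes were higher and 2554 lower in luminal-like cells, 4898 of 11630 tested, and 4262 of the 9635 genes not used for clustering differed. Without replicate 3, which held most luminal-like cells, 2918 genes differed. Of the differing genes 47.9% were higher, against 58.6% with RLE size factors, 58.9% with DESeq2 and 69.4% with library size alone.

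**Figure D3:**
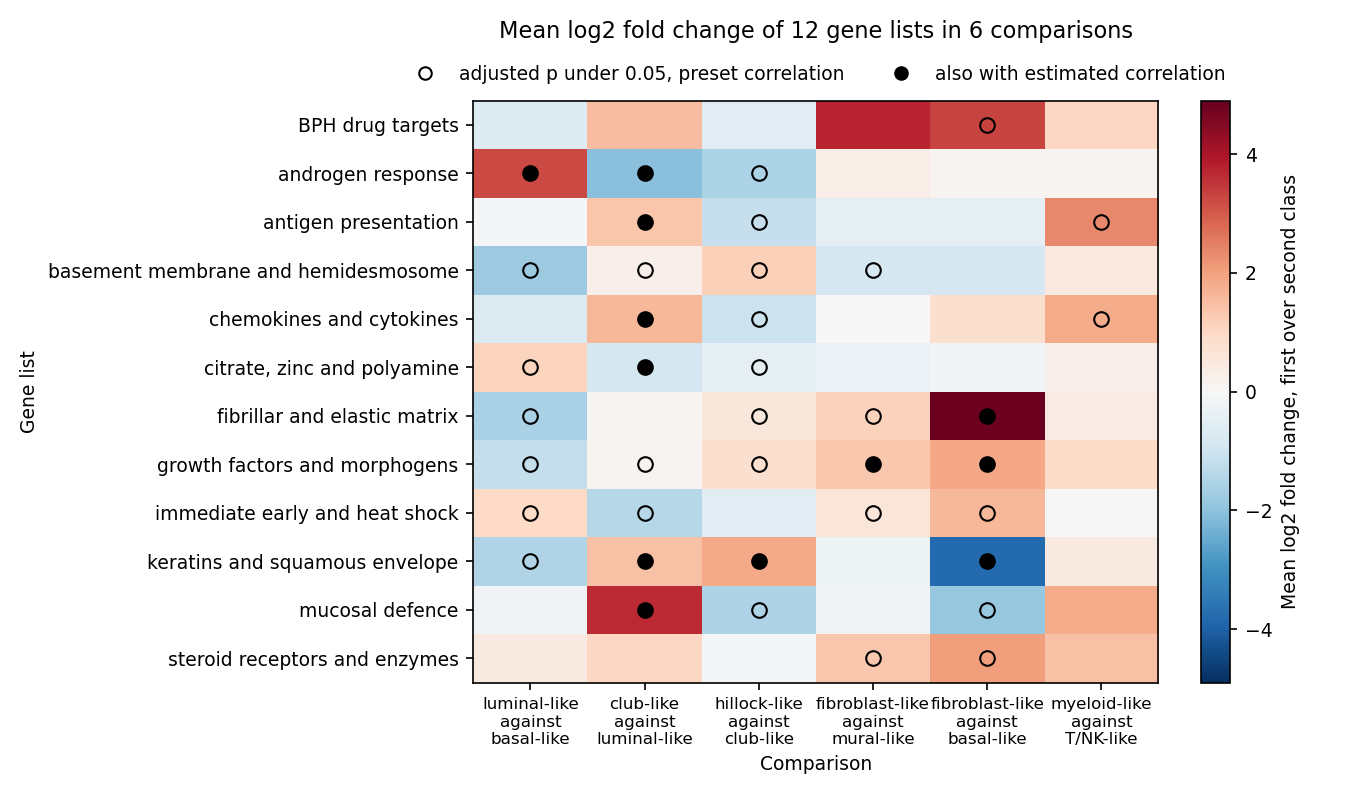
Fitted mean log2 fold change (colour) of 12 gene lists (vertical axis) in 6 comparisons (horizontal axis), first class over second; circles mark a camera adjusted p under 0.05 with the preset correlation, filled where it also held with an estimated correlation. Of 72 results, 39 were called and 12 of these held.

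Club-like cells, set against luminal-like cells, had the mucosal defence, chemokine, antigen presentation and keratin lists called higher and the androgen response and citrate, zinc and polyamine lists called lower. With an estimated correlation these 6 calls held, with an adjusted p of at most 0.024. BPIFB1 (ENSG00000125999), a secreted protein of airway mucosa, averaged 159 ± 189 normalised CPM in club-like and 1.18 ± 0.917 in luminal-like cells (SD, n = 3). It lies on chromosome 20 from 33273480 to 33309878. SAA1 averaged 347 ± 261 CPM in club-like and 3.81 ± 1.55 in luminal-like cells, and CD74 1200 ± 759 and 134 ± 66.6. Without replicate 2 the club-like means were 51.1, 197 and 776 CPM, and BPIFB1 averaged 0.663 in luminal-like cells. The genes named here passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in the same direction in 3 of 3 specimens, with adjusted p of at most 0.0292.

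Mucosal defence genes were higher in club-like cells for 21 of 24 members and lower for none (22 higher adjusted over the list alone), with a median log2 fold change of 3.64 and a camera adjusted p = 1.4e-18. Chemokines and cytokines had 19 of 39 members higher and 1 lower (20 and 1 adjusted over the list alone; median 1.66, camera adjusted p = 8.3e-08). CXCL6 was higher by 5.42 ± 0.49 (log2, SE). CSF2, the granulocyte-macrophage growth factor, had 402 counts in club-like and 2 in luminal-like cells, a ratio of 141 with a 95% counting interval of 38.8 to 1170. Antigen presentation genes had 12 of 23 members higher and none lower (14 adjusted over the list alone; median 1.01, camera adjusted p = 1.5e-08), with CD74 higher by 3.05 ± 0.37 and HLA-DQA1 by 3.16 ± 0.45. Keratins and squamous envelope genes had 11 of 20 higher and 1 lower (15 and 1 adjusted over the list alone; median 1.05, camera adjusted p = 1.9e-06), led by KRT23 (4.42 ± 0.52) and KRT7 (4.13 ± 0.45).

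Of the androgen response list, 20 of 26 members were lower in club-like cells and 1 higher, as adjusted over the list alone (median -2.10, camera adjusted p = 2.7e-14). TMEFF2 differed by -4.99 ± 0.68 and SPON2, a secreted matrix protein, by -4.79 ± 0.58. The median of the list stayed above that of T/NK-like cells, though single members such as TMEFF2 ranged from 0.0% to 6.95% of the luminal-like level. Over 14 members abundant in luminal-like cells, the median club-like share of the luminal-like level was 20.1%, 6.90% and 12.6% in replicates 1 to 3. In T/NK-like cells it was 0.732%, 1.17% and 2.56%. The club-like cluster of replicate 1, of 268 cells, was a near tie, at 0.697 for club and 0.629 for luminal markers. The luminal marker KLK3 stood at 0.195% to 8.41% of its luminal-like level in club-like cells. Citrate, zinc and polyamine genes had 11 of 27 members lower and 1 higher (13 and 1 adjusted over the list alone; median -0.90, camera adjusted p = 1.6e-05), among them SLC30A4 (-3.89 ± 0.43) and the zinc importer SLC39A10 (-2.82 ± 0.36). Immediate early and heat shock genes had 19 of 26 members lower and 2 higher (20 and 2 adjusted over the list alone; median -1.45, camera adjusted p = 4.2e-11, adjusted p = 0.052 with an estimated correlation), such as EGR3 (-3.15 ± 0.46) and EGR2 (-3.08 ± 0.61). A stress-led cluster held 404 of the 1188 luminal-like cells of replicate 3.

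Basement membrane genes had 7 of 27 members higher and 2 lower, the same over the list alone (median 0.27, camera adjusted p = 0.047), a call lost in 4 of 17 alternatives and with an adjusted p = 0.32 with an estimated correlation. LAMB3 was higher by 3.64 ± 0.38 and ITGA2, a collagen-binding integrin, by 2.39 ± 0.40, which did not pass with minimums of 200 genes and 500 UMIs (1.13, edgeR adjusted p = 0.122). Growth factors and morphogens had 12 of 46 members higher and 5 lower (14 and 6 adjusted over the list alone; median 0.02, or 0.00 with members at their bound, camera adjusted p = 0.047), lost in 5 of 17 alternatives, with adjusted p = 0.27 with an estimated correlation. IGFBP3 was higher by 4.35 ± 0.55 and the Wnt inhibitor DKK1 by 4.30 ± 0.55. No call was made for fibrillar and elastic matrix (4 higher and 1 lower of 28, as over the list alone, camera adjusted p = 0.97) or steroid receptors and enzymes (4 and 3 of 15; 6 and 3 over the list alone, adjusted p = 0.15, called in 1 of 17 alternatives, fry). COL6A2 differed by -1.58 ± 0.33. The calls of FN1, fibronectin (2.23 ± 0.74, edgeR adjusted p = 0.0275, higher in 3 of 3 specimens), and of SULT2B1 (-0.98 ± 0.32, edgeR adjusted p = 0.0292, lower in 3 of 3) were lost in 7 and 8 of 17 alternatives, among them without replicates 1, 2 and 3 (edgeR adjusted p = 0.0901, 0.0612 and 0.0720 for FN1, and 0.143, 0.0584 and 0.164 for SULT2B1). The basement membrane list was not called without replicate 2 (camera adjusted p = 0.113), nor the growth factor list without replicate 1 or 2 (0.225 and 0.0950), and the mean of the latter turned from 0.15 to -0.03 without replicate 1 and to -0.008 with no doublets removed. Outside the lists, CRABP2, which binds retinoic acid (4.40 ± 0.42), the integrin chain ITGB6 (4.30 ± 0.50) and ASS1, of arginine synthesis (3.97 ± 0.44), were higher. SCD (-4.32 ± 0.46), the matrix receptor ANTXR2 (-3.49 ± 0.43) and the peptide-processing enzyme CPE (-3.15 ± 0.54) were lower.

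The test called 1291 genes higher and 1308 lower in club-like cells, 2599 of 11630, and 2131 of the 9635 genes not used for clustering. The count was 1199 without replicate 2, 1228 without replicate 3, 1448 without the specimen block and 1509 with minimums of 200 genes and 500 UMIs. The share of higher genes, 49.7%, was 39.7% with RLE size factors and 39.0% with DESeq2.

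Hillock-like cells, set against club-like cells, had the keratin and squamous envelope list called higher, the 1 list whose call held with an estimated correlation (adjusted p = 0.0099). KRT6A (ENSG00000205420), a stress keratin of stratified epithelia, averaged 606 ± 385 normalised CPM in hillock-like and 3.44 ± 2.41 in club-like cells (SD, n = 3). It lies on chromosome 12 from 52487174 to 52493257. S100A2 averaged 6463 ± 1375 CPM in hillock-like and 137 ± 55.0 in club-like cells, and COL17A1 22.3 ± 9.45 and 0.506 ± 0.591. TFF1 averaged 8.65 ± 7.08 CPM in hillock-like and 510 ± 402 in club-like cells. Without replicate 3, TFF1 averaged 5.03 and 305 CPM and COL17A1 0.181 in club-like cells, and without replicate 2, KRT6A averaged 2.17 in club-like cells. For each gene named for this pair, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was passed with the same direction in 3 of 3 specimens and an adjusted p of at most 0.035.

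Keratins and squamous envelope genes had 10 of 20 members higher and 2 lower in hillock-like cells (11 and 2 adjusted over the list alone; median log2 fold change 1.80, camera adjusted p = 8.0e-09). KRT6A was higher by 7.64 ± 0.61 (log2, SE) and S100A2 by 5.63 ± 0.44. Basement membrane and hemidesmosome genes had 12 of 27 higher and none lower (14 adjusted over the list alone; median 0.95, camera adjusted p = 3.4e-05, adjusted p = 0.081 with an estimated correlation), with COL17A1 higher by 4.86 ± 0.60 and the hemidesmosomal integrin ITGA6 by 2.93 ± 0.35. In replicate 3 the hillock-like cluster of 582 cells scored 0.579 for basal and 0.505 for hillock markers, and over all specimens the basal markers KRT5 and KRT15 averaged 868 ± 237 and 2110 ± 1370 CPM in hillock-like against 526 ± 164 and 544 ± 222 in basal-like cells. Growth factors and morphogens had 13 of 46 higher and 1 lower (14 and 2 adjusted over the list alone; median 0.65, or 0.56 with members at their bound, camera adjusted p = 1.0e-04, adjusted p = 0.072 with an estimated correlation). EREG, a ligand of the EGF receptor, was higher by 4.34 ± 0.62 and IGFBP7 by 3.27 ± 0.29. Fibrillar and elastic matrix genes had 3 of 28 higher and none lower (2 adjusted over the list alone; median 0.68, or 0.36 with members at their bound, camera adjusted p = 0.026), lost in 7 of 17 alternatives, with adjusted p = 0.20 with an estimated correlation and a camera adjusted p = 0.238 without replicate 3. Its mean, 0.54, turned to -0.25 at resolution 0.6. TNC, tenascin C, was higher by 2.86 ± 0.45 and TIMP3 by 2.58 ± 0.48.

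Mucosal defence genes had 11 of 24 members lower and 4 higher (11 and 5 adjusted over the list alone; median -0.74, camera adjusted p = 8.5e-04, adjusted p = 0.081 with an estimated correlation). BPIFB1 had 1 count in hillock-like and 2475 in club-like cells, a ratio of 1320 in favour of club-like cells with a 95% counting interval of 237 to 52100, and TFF1 differed by -5.99 ± 0.58. Antigen presentation genes had 10 of 23 lower and none higher (13 and 1 adjusted over the list alone; median -0.71, camera adjusted p = 1.6e-06, adjusted p = 0.072 with an estimated correlation), with HLA-DQA1 at -3.12 ± 0.42 and HLA-DPA1 at -2.70 ± 0.41. The androgen response list had 13 of 26 lower and 1 higher (17 and 1 adjusted over the list alone; median -1.64, camera adjusted p = 3.4e-05, adjusted p = 0.072 with an estimated correlation). STEAP4, a metalloreductase, differed by -5.09 ± 0.77 and SLC45A3 by -4.08 ± 0.94, a call lost in 2 of 16 alternatives, among them without replicate 1 (-1.81, edgeR adjusted p = 0.23). Chemokines and cytokines had 10 of 39 lower and 2 higher (12 and 2 adjusted over the list alone; median -1.0, or -0.68 at the bound, camera adjusted p = 0.0063), lost in 2 of 17 alternatives, with adjusted p = 0.19 with an estimated correlation. CSF2 differed by -2.94 ± 0.70 and fractalkine CX3CL1 by -2.46 ± 0.42. Citrate, zinc and polyamine genes had 7 of 27 lower and 1 higher (8 and 2 adjusted over the list alone; median -0.30, camera adjusted p = 0.043), lost in 8 of 17 alternatives, with adjusted p = 0.19 with an estimated correlation. The metallothioneins MT1F and MT1G differed by -2.35 ± 0.39 and -2.23 ± 0.48. The calls of CSF2 and MT1G were lost in 2 and 3 of 17 alternatives, among them without replicate 3 (-1.82, edgeR adjusted p = 0.262, and -1.68, adjusted p = 0.109). Without replicate 3 the chemokine and citrate lists were not called (camera adjusted p = 0.114 and 0.101). The citrate list was not called without replicate 1 either (0.243).

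No call was made for immediate early and heat shock genes (2 higher and 4 lower of 26; 3 and 5 adjusted over the list alone, camera adjusted p = 0.17) or steroid receptors and enzymes (2 and 4 of 15; 2 and 5 over the list alone, adjusted p = 0.79). MYC was higher by 1.85 ± 0.40, HSPA6 differed by -3.46 ± 0.94, and HSD17B11, a steroid dehydrogenase, by -1.61 ± 0.34. SRD5A3, of dolichol synthesis, differed by -1.38 ± 0.46 (edgeR adjusted p = 0.035, lower in 3 of 3 specimens), a call lost in 10 of 17 alternatives, among them without replicate 2 or 3 (edgeR adjusted p = 0.161 and 0.494). Without replicate 3, HSPA6 (-4.05, edgeR adjusted p = 0.0532) and HSD17B11 (-1.44, adjusted p = 0.0578) did not pass. The immediate early and heat shock list was called lower in 4 of 17 alternatives, among them without replicate 2 (camera adjusted p = 0.00253). Outside the lists, the epithelial regulator CLCA2 (6.22 ± 0.51), the serpin SERPINB5 (3.74 ± 0.32) and the actin bundler FSCN1 (3.36 ± 0.37) were higher. SLC44A4 (-3.69 ± 0.33), the phospholipase PLA2G16 (-3.31 ± 0.42) and the cochaperone DNAJC12 (-3.27 ± 0.48) were lower. Of 11630 genes, 960 were higher and 1120 lower in hillock-like cells, 2080 together (810 and 1343 with library size alone), with 1716 of them among the 9635 not used for clustering. The count was 669 without replicate 3, 1097 without replicate 2, 1076 without the specimen block and 1261 with a mitochondrial limit of 20%.

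**Figure D4:**
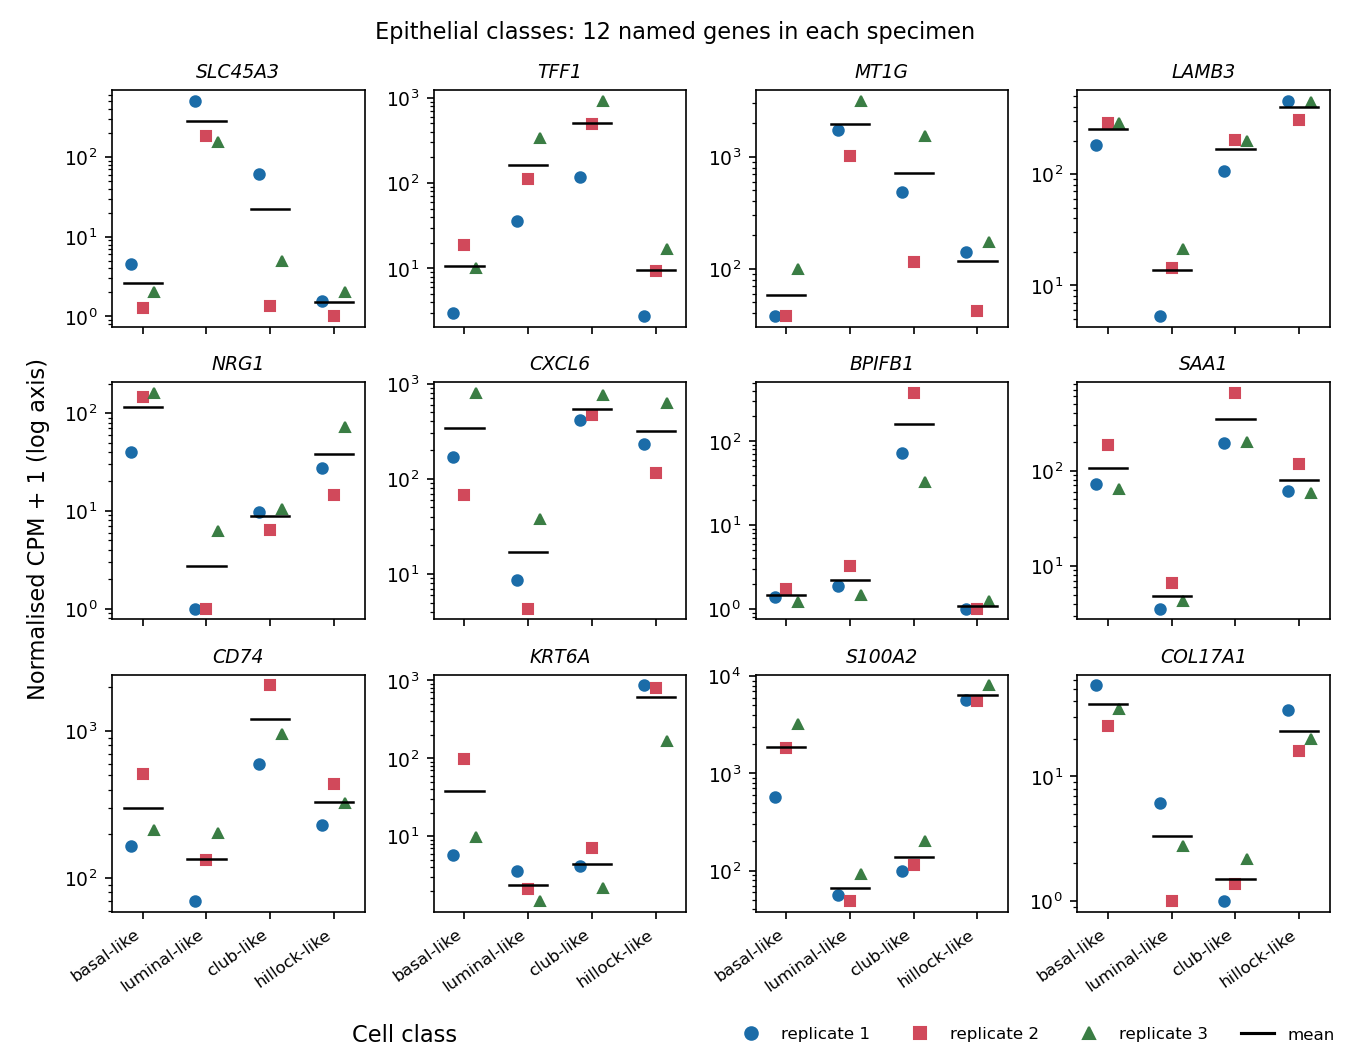
Normalised CPM + 1 (log axis) of 12 named genes in the 4 epithelial classes; symbols are the 3 specimens and bars their means. SLC45A3 averaged 283 CPM in luminal-like cells, BPIFB1 159 CPM in club-like cells and KRT6A 606 CPM in hillock-like cells.

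Between the stromal classes, the growth factor and morphogen list was called higher in fibroblast-like cells, the 1 list whose call held with an estimated correlation (adjusted p = 0.030). SRD5A2 averaged 52.6 ± 39.0 normalised CPM in fibroblast-like cells (SD, n = 3) and had 131 counts against 0 in mural-like cells, at least 68.9-fold higher with the floor of 3 counts over the class. SRD5A2 averaged 30.8 CPM without replicate 1. HSD11B1, which regenerates cortisol from cortisone, averaged 284 ± 164 CPM in fibroblast-like and 3.06 ± 1.80 in mural-like cells. WNT2 (ENSG00000105989), a Wnt ligand on chromosome 7 from 117275451 to 117323289, had 210 counts against 0, at least 110-fold higher. CCL8, a monocyte chemokine, had 0 counts in fibroblast-like and 521 in mural-like cells, at least 110-fold lower, and averaged 75.3 CPM there without replicate 3 against 124 in all. Genes named for this comparison passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and went the same way in 3 of 3 specimens (adjusted p of at most 0.0346), but CCL8, WNT2 and RSPO3 did not pass with DESeq2 (adjusted p = 0.115, 0.407 and 0.247).

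Growth factors and morphogens had 21 of 46 members higher and 4 lower in fibroblast-like cells (23 and 5 adjusted over the list alone; median log2 fold change 1.30, also at the bound, camera adjusted p = 4.8e-07). RSPO3, which amplifies Wnt signals, had 1 count in mural-like cells, a ratio of 194 with a 95% counting interval of 34.2 to 7730. Fibrillar and elastic matrix genes had 9 of 28 higher and 1 lower (13 and 2 adjusted over the list alone; median 0.79, camera adjusted p = 0.0013, adjusted p = 0.19 with an estimated correlation). EFEMP1, a fibulin, was higher by 5.35 ± 0.85 (log2, SE) and MMP2 by 4.68 ± 0.49. Steroid receptors and enzymes had 3 of 15 higher and 1 lower, as adjusted over the list alone (median 0.58, camera adjusted p = 0.020), lost in 1 of 17 alternatives, with adjusted p = 0.22 with an estimated correlation. HSD11B1 was higher by 6.55 ± 0.50. Immediate early and heat shock genes had 7 of 26 higher and 1 lower, also adjusted over the list alone (median 0.52, camera adjusted p = 0.0041), lost in 1 of 17 alternatives, fry, with adjusted p = 0.56 with an estimated correlation. EGR2 was higher by 3.61 ± 0.70 and EGR1 by 1.87 ± 0.50, a call lost in 2 of 17 alternatives, among them without replicate 3 (1.47, edgeR adjusted p = 0.167). Basement membrane genes had 12 of 27 lower and none higher, as over the list alone (median -0.98, camera adjusted p = 0.0041), lost without replicate 1 (camera adjusted p = 0.0609), with adjusted p = 0.29 with an estimated correlation. LAMA5, a laminin chain, had 3 counts in fibroblast-like and 90 in mural-like cells, a ratio of 19.0 in favour of mural-like cells (95% counting interval 6.30 to 93.9), and the type IV collagen COL4A1 differed by -2.37 ± 0.44.

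The BPH drug target list, of which 3 of 10 members were tested, was not called (1 higher, SRD5A2, as over the list alone, camera adjusted p = 0.052), nor were chemokines and cytokines (7 higher and 5 lower of 39; 9 and 5 adjusted over the list alone, adjusted p = 0.51, called in 1 of 17 alternatives). CXCL13, which attracts B cells, had 653 counts in fibroblast-like and 2 in mural-like cells, a ratio of 515 (95% counting interval 142 to 4260). No call was made for antigen presentation (2 and 4 of 23, as over the list alone, adjusted p = 0.079), androgen response (4 and 3 of 26, likewise, adjusted p = 0.51), citrate, zinc and polyamine (2 and 6 of 27; 3 and 7 over the list alone, adjusted p = 0.64), keratins (4 and 1 of 20; 4 and 2 over the list alone, adjusted p = 0.75) or mucosal defence (1 and 0 of 24, likewise, adjusted p = 0.91). The androgen list held members in both directions, with STEAP2 at 3.82 ± 0.61 and STEAP4 at -5.41 ± 0.62. HLA-B differed by -1.18 ± 0.20, MT1X by -2.27 ± 0.59, MT1F by -2.14 ± 0.49 (not passing without the specimen block, edgeR adjusted p = 0.0748) and KRT18 by -2.56 ± 0.43, while complement C3 was higher by 5.71 ± 0.78. The calls of HLA-DPA1 (1.32 ± 0.44, edgeR adjusted p = 0.0346, higher in 3 of 3 specimens) and CSTA (2.07 ± 0.68, edgeR adjusted p = 0.0322, higher in 3 of 3) were lost in 3 of 17 and 4 of 16 alternatives, among them without replicates 1 and 3 for HLA-DPA1 (adjusted p = 0.0938 and 0.494) and without replicates 2 and 3 for CSTA (adjusted p = 0.313 and 0.0872). The drug target list was called higher in 8 of 16 alternatives, among them without replicate 2 (camera adjusted p = 0.00201). Antigen presentation was called lower in 2 of 17, without replicate 3 (mean log2 fold change -0.71 against -0.43, camera adjusted p = 0.0412) and with no filter on low counts (0.00701). Outside the lists, MGST1, of glutathione conjugation (4.47 ± 0.39), SERPINF1, an antiangiogenic serpin (3.30 ± 0.42), and the matrix protein MATN2 (3.30 ± 0.40) were higher, and TINAGL1 (-4.45 ± 0.53), the laminin receptor BCAM (-4.30 ± 0.38) and the guidance ligand SLIT3 (-3.50 ± 0.53) lower.

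The test called 958 genes higher and 1074 lower in fibroblast-like cells, 2032 of 11630, with 1532 among the 9635 genes not used for clustering. Without replicate 3, which held 253 of the 401 fibroblast-like cells, 657 genes differed, and 1220 without the specimen block. The share of higher genes, 47.1%, was 53.7% with RLE size factors and 68.9% with library size alone.

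Between fibroblast-like and basal-like cells, the stroma and the epithelium that faces it, the fibrillar matrix and growth factor lists were called higher and the keratin list lower in fibroblast-like cells. With an estimated correlation these 3 calls held (adjusted p = 6.1e-05, 0.022 and 0.0032). SFRP2 (ENSG00000145423), a secreted Wnt modulator, averaged 452 ± 224 normalised CPM in fibroblast-like and 0.133 ± 0.116 in basal-like cells (SD, n = 3). It lies on chromosome 4 from 153780592 to 153789120. IGF1, a mitogen for epithelium, averaged 714 ± 244 and 0.448 ± 0.297 CPM, and CXCL12, which retains leukocytes, 182 ± 78.6 and 0.294 ± 0.194. HSPA6 averaged 1998 ± 1011 CPM in fibroblast-like and 111 ± 169 in basal-like cells, the latter 13.3 without replicate 1. All named genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and moved the same way in 3 of 3 specimens (adjusted p of at most 0.0183). PGR and CD74 did not pass with DESeq2 (adjusted p = 0.257 and 0.0785).

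Fibrillar and elastic matrix genes had 23 of 28 members higher and none lower in fibroblast-like cells (25 and 1 adjusted over the list alone; median log2 fold change 4.47, camera adjusted p = 1.1e-21), with COL1A2 higher by 10.12 ± 0.51 (log2, SE) and the microfibril protein MFAP4 by 9.85 ± 0.45. Growth factors and morphogens had 22 of 46 higher and 12 lower (28 and 14 adjusted over the list alone; median 1.32, camera adjusted p = 2.2e-06), with SFRP2 higher by 11.63 ± 0.73 and IGF1 by 10.67 ± 0.61. Keratins and squamous envelope genes had 15 of 20 lower and none higher, as over the list alone (median -4.32, or -4.16 with members at their bound, camera adjusted p = 5.7e-10). KRT6A had 1 count in fibroblast-like and 2260 in basal-like cells, a ratio of 134 in favour of basal-like cells (95% counting interval 23.9 to 5280), and the desmosomal cadherin DSC3 had 2 and 1411, a ratio of 41.7 (11.5 to 345). Steroid receptors and enzymes had 8 of 15 higher and 1 lower, as over the list alone (median 1.90, camera adjusted p = 0.0018, adjusted p = 0.060 with an estimated correlation). HSD11B1 was higher by 10.98 ± 0.56 and PGR by 5.99 ± 0.86. Of the drug targets, 2 of the 3 tested were higher, likewise over the list alone, PDE5A by 5.61 ± 0.43 and SRD5A2 by 5.56 ± 0.56 (camera adjusted p = 0.016), a list call lost in 3 of 17 alternatives, among them without replicates 1 and 3 (0.0793 and 0.0620), with adjusted p = 0.060 with an estimated correlation.

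Immediate early and heat shock genes had 19 of 26 members higher and 1 lower (20 and 1 adjusted over the list alone; median 1.60, camera adjusted p = 2.9e-07, adjusted p = 0.16 with an estimated correlation). HSPA6 was higher by 5.20 ± 0.97 and its partner DNAJB1 by 3.78 ± 0.67. Mucosal defence genes had 8 of 24 lower and 3 higher (10 and 3 adjusted over the list alone; median -1.45, or -1.31 at the bound, camera adjusted p = 0.026), lost in 2 of 17 alternatives, with adjusted p = 0.25 with an estimated correlation. SAA1 differed by -5.20 ± 0.46 and the defensin DEFB1 by -4.88 ± 0.59. No call was made for basement membrane genes (9 higher and 13 lower of 27; 9 and 14 adjusted over the list alone, camera adjusted p = 0.083), although the laminin chains LAMA4 and LAMB3 differed by 6.43 ± 0.50 and -5.88 ± 0.50. Nor was one made for chemokines and cytokines (15 and 7 of 39, as over the list alone, adjusted p = 0.086, called higher in 5 of 17 alternatives), androgen response (6 and 4 of 26, likewise, adjusted p = 0.82), citrate, zinc and polyamine (4 and 6 of 27, likewise, adjusted p = 0.82) or antigen presentation (5 and 2 of 23, likewise, adjusted p = 0.89, called in 1 of 17 alternatives). CXCL13 was higher by 9.75 ± 1.10, CXCL12 by 9.20 ± 0.75, SPON2 by 7.58 ± 0.66, the transcription factor ZBTB16 by 2.33 ± 0.58, MT1M by 2.80 ± 0.54 and HLA-DPA1 by 1.61 ± 0.40. ODC1, the first enzyme of polyamine synthesis, differed by -2.96 ± 0.40. CD74 differed by -1.07 ± 0.36 (edgeR adjusted p = 0.0183, lower in 3 of 3 specimens), a call lost in 9 of 17 alternatives, and its sign turned, to 0.19, with no doublets removed. CD74 did not pass without replicate 2 or 3 (-0.82 and -1.11, edgeR adjusted p = 0.102 and 0.0831). Nor did ZBTB16 (1.74, adjusted p = 0.0798) and HLA-DPA1 (1.24, adjusted p = 0.0897) without replicate 3, and ZBTB16 without the specimen block (1.25, adjusted p = 0.479). The basement membrane list was called lower in 5 of 17 alternatives, among them without replicate 2 (camera adjusted p = 0.0402). Outside the lists, VAMP5 (4.93 ± 0.34), the inflammasome sensor NLRP1 (4.39 ± 0.38) and the actin-severing GSN (4.05 ± 0.45) were higher, and the serpin SERPINB5 (-5.55 ± 0.46) and the focal adhesion protein TES (-5.35 ± 0.47) lower.

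Of 11630 genes, 2026 were higher and 2298 lower in fibroblast-like cells, 4324 together, with 3466 among the 9635 not used for clustering. Without replicate 3 the count was 2420. The share of higher genes, 46.9%, was 59.8% with RLE size factors, 61.5% with DESeq2 and 69.4% with library size alone.

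**Figure D5:**
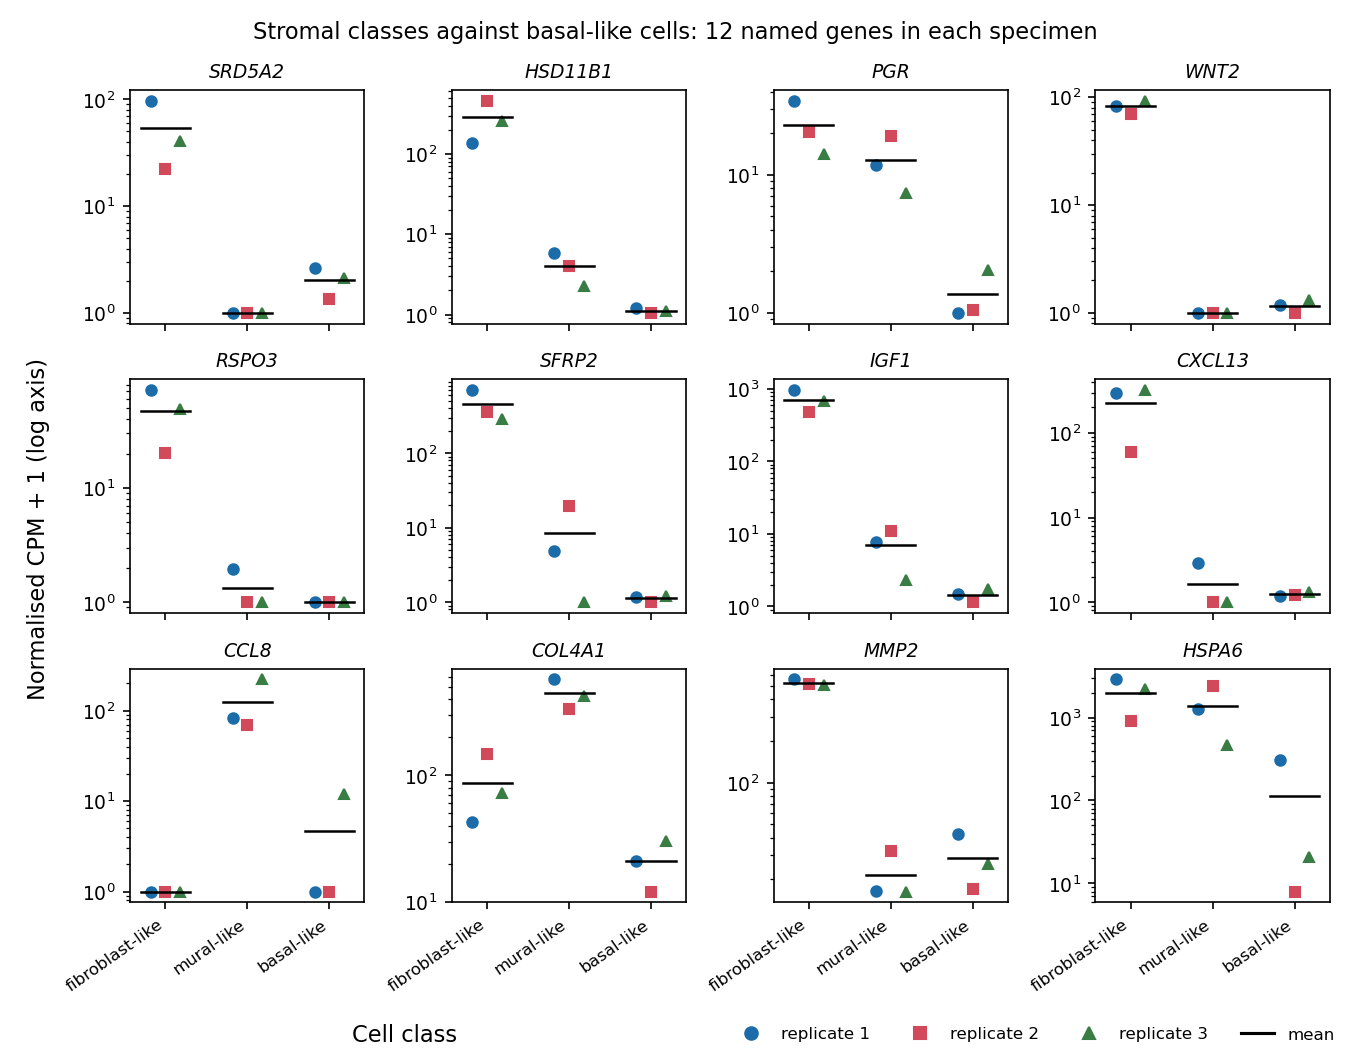
Normalised CPM + 1 (log axis) of 12 named genes in fibroblast-like, mural-like and basal-like cells; symbols are the 3 specimens and bars their means. SRD5A2 averaged 52.6 CPM and IGF1 714 CPM in fibroblast-like cells, and CCL8 124 CPM in mural-like cells.

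Among leukocytes, myeloid-like cells carried more HLA-DRA, LYZ and EREG transcripts than T/NK-like cells and less of NR3C1, the glucocorticoid receptor, and no list call held with an estimated correlation (adjusted p of at least 0.62). HLA-DRA (ENSG00000204287) averaged 16790 ± 4097 normalised CPM in myeloid-like and 161 ± 33.9 in T/NK-like cells (SD, n = 3). It lies on chromosome 6 from 32439842 to 32445046. LYZ, lysozyme, averaged 2303 ± 1866 and 9.45 ± 3.54 CPM, and EREG 1370 ± 937 and 15.3 ± 12.2. Without replicate 3, LYZ averaged 1230 CPM in myeloid-like cells, and without replicate 1, EREG averaged 8.37 in T/NK-like cells. A cluster of 171 cells of replicate 1 that scored highest for myeloid markers stayed unnamed and is not in these levels. In plain CPM, EREG stood at 4110 and LYZ at 5500 there, against 270 and 1050 in the myeloid-like cells of that specimen. NR3C1 averaged 85.7 ± 5.84 CPM in myeloid-like and 334 ± 112 in T/NK-like cells. Every gene named for the leukocytes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p of at most 0.0336) and moved the same way in 3 of 3 specimens.

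Antigen presentation genes had 11 of 23 members higher and 6 lower in myeloid-like cells (11 and 8 adjusted over the list alone, camera adjusted p = 0.0092), lost in 1 of 17 alternatives, with adjusted p = 0.62 with an estimated correlation. The list's mean log2 fold change was 2.36 and its median -0.10. HLA-DRA was higher by 6.70 ± 0.40 (log2, SE), and HLA-DOA had 271 counts against 1, a ratio of 153 with a 95% counting interval of 27.3 to 6070. Chemokines and cytokines had 17 of 39 higher and 5 lower (18 and 5 adjusted over the list alone; median 0.81, camera adjusted p = 0.030), lost in 3 of 17 alternatives, among them without replicates 1 and 3 (0.0642 and 0.0755), with adjusted p = 0.62 with an estimated correlation. CXCL5 had 187 counts against 0 in T/NK-like cells, at least 35.2-fold higher, and CXCL12 262 against 0, at least 49.4-fold higher. Mucosal defence genes had 5 of 24 higher and none lower, as over the list alone, and were not called (camera adjusted p = 0.070), but were called higher in 6 of 17 alternatives. LYZ was higher by 7.78 ± 0.66, and S100A8, a subunit of calprotectin, had 232 counts against 1, a ratio of 131 (95% counting interval 23.3 to 5200).

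Growth factors and morphogens had 9 of 46 members higher and 3 lower, as over the list alone (camera adjusted p = 0.35, called in 2 of 17 alternatives), with EREG higher by 6.59 ± 0.66 and IGF1 at 180 counts against 3, a ratio of 33.9 (95% counting interval 11.4 to 166). Steroid receptors and enzymes had 4 of 15 higher and 1 lower, likewise (camera adjusted p = 0.67). DHRS9, a retinol dehydrogenase, had 130 counts against 0, at least 24.5-fold higher, and NR3C1 differed by -1.94 ± 0.26. No call was made for citrate, zinc and polyamine (7 higher and 2 lower of 27, camera adjusted p = 0.67), immediate early and heat shock (3 and 4 of 26, adjusted p = 0.67), keratins (3 and 0 of 20, adjusted p = 0.67) or basement membrane genes (0 and 0 of 27, adjusted p = 0.67), each with the same counts adjusted over the list alone. Nor was one made for fibrillar and elastic matrix (3 and 1 of 28; 3 and 0 over the list alone, adjusted p = 0.67) or androgen response (4 and 1 of 26; 3 and 0 over the list alone, adjusted p = 0.93). SAT1, of polyamine breakdown, was higher by 2.29 ± 0.24, the metalloproteinase inhibitor TIMP1 by 4.05 ± 0.39, thrombospondin THBS1 by 3.83 ± 0.64 and KLF4 by 3.94 ± 0.48. IER3 was higher by 3.90 ± 0.44, ACSL3, of fatty acid activation, by 2.33 ± 0.30, and the cystatins CSTA and CSTB by 3.82 ± 0.56 and 2.09 ± 0.30, while MT1F differed by -2.12 ± 0.41. The transcription factor MAF differed by -1.05 ± 0.37 (edgeR adjusted p = 0.0336, lower in 3 of 3 specimens), a call lost in 4 of 17 alternatives, among them without replicate 2 (-0.57, edgeR adjusted p = 0.425). Outside the lists, RAB31 (658 counts against 3; ratio 124, 95% counting interval 42.2 to 603), the lectin CD302 (669 against 3; ratio 126, 42.9 to 613) and the cytokine receptor IL13RA1 (5.38 ± 0.52) were higher. The lymphoid transcription factor ETS1 (-4.66 ± 0.45), IFITM1 (-4.32 ± 0.46) and ODF2L (-3.35 ± 0.28) were lower.

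The test called 1885 genes higher and 1434 lower in myeloid-like cells, 3319 of 11630 (1621 and 1768 with library size alone), with 2366 among the 9635 not used for clustering. Without replicate 3 the count was 1902.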

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

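Of the tests in this part, those without stress-led clusters, on luminal-like cells as the whole of the androgen signal, on doublets with basal-like cells, and on other splits of the samples were chosen after the result was seen. Because the design has 1 group, no biological explanation was tested for any pattern.

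Cells that the comparisons did not use formed 5 clusters that could not be named. In replicate 1, a cluster of 556 cells (11.2% of the kept cells) was led by DKK1 and KRT17 and scored highest for basal markers, but the club marker SCGB1A1 was among its leading genes. A second cluster of replicate 1 held 171 cells (3.45%) led by EREG and LYZ and scored highest for myeloid markers, with the hillock marker APOBEC3A, which myeloid cells also express, among its leading genes. The last cluster of replicate 1 held 15 cells led by GZMB and CCR7 and scored under the minimum for every class. In replicate 2, a cluster of 146 cells (2.17%) was led by CHGA together with the stress genes ATF3, JUN and FOS, and CHGA reached 399 CPM against 0.122 in the basal-like cells of the same specimen. Its scores for basal and neuroendocrine markers, 0.736 and 0.681, were a near tie. In the same replicate 682 cells (10.2%) led by TFF1 and SPINK1 scored 0.630 for club and 0.494 for luminal markers.

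The cluster led by TFF1 and SPINK1 was tested against doublets and damage. Doublets of club-like and luminal-like cells cannot exceed both sources, yet 14 genes of at least 100 CPM lay over 2 times above both, with TFF1 at 2070 CPM against 594 and 140, and SPINK1 at 458 against 111 and 96.4. Damaged cells would raise the mitochondrial share, but its median of 3.26%, above the specimen's median of 2.98%, lay below the 75th percentile of 3.99% set as the bound. Of the 14, ODC1, CCL2, KRTAP3-1 and ETS2 were higher still in basal-like cells and 9 lay over 2 times above all 3 classes. Doublets with basal-like cells would bring their abundant transcripts, but these stood at a median of 7.61% of the basal-like level (3.77% to 19.4% over 15 genes), with 25% set as the bound, which leaves only a smaller share open.

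Immediate early and heat shock genes were called higher in fibroblast-like than in basal-like cells (camera adjusted p = 2.9e-07, adjusted p = 0.16 with an estimated correlation). Clusters led by stress genes held 251 basal-like and 0 of the 401 fibroblast-like cells. Of these 2 classes, they lay only in the one where the list was lower. Leaving them out gave a mean log2 fold change of 1.71 against 1.64. With 0 fibroblast-like cells in them, these clusters did not add to the higher level of the list. Leaving out stress-led cells of the lower class alone could hardly narrow the difference, so the test itself decides nothing. It says nothing on stress in fibroblast-like cells outside these clusters. Among cells with at most 5% mitochondrial UMIs the difference was at least 97.3% of that among all kept cells in each of the 3 specimens, which argues against a high mitochondrial share. The limit removed 13 of the 401 fibroblast-like and 1508 of the 7341 basal-like cells. A response to the 4 h digestion that differs between cell classes cannot be told apart from a difference in the tissue, since 0 samples were left undigested.

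Androgen response genes stood between the basal-like and luminal-like levels in club-like cells. Free RNA from luminal-like cells would also reach T/NK-like cells, where KLK3 averaged 102 CPM against 43.3 in basal-like and 29.6 in hillock-like cells, but the club-like share of the luminal-like level was at least 4.94 times the T/NK-like share in each of the 3 specimens. If luminal-like cells or doublets counted as club-like made up the whole signal, MSMB, KLK3 and ACPP should stand near the list's share. The highest of the 3 reached at most 41.8% of the list's median share (9.87% and 36.4% in the other specimens). But these 3 are naming markers and were open to the clustering, while list genes were kept out of it. Luminal-like cells low in the 3 may thus sit among club-like cells, so a low share does not decide this. A contribution in part cannot be told apart from expression in club-like cells: the 25th percentile over abundant luminal transcripts outside the list was 39.4%, 2.76% and 22.1% of the list's median share in replicates 1, 2 and 3. Values under 25% in every specimen would have argued against it, and replicate 1, whose club-like cluster was a near tie with luminal markers, lay above.

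The counts of genes that differed were compared with other splits of the same pseudobulks, for which 3 against 3 allows 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. Because the classes were formed from the expression of the same cells, the real split was bound to lead, so these counts decide nothing. The real count and the highest of the other splits were 4898 and 25 for luminal-like against basal-like, 2599 and 5 for club-like against luminal-like, and 2080 and 3 for hillock-like against club-like cells. They were 2032 and 1 for fibroblast-like against mural-like, 4324 and 1 for fibroblast-like against basal-like, and 3319 and 1 for myeloid-like against T/NK-like cells.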

How the results depend on the processing

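The alternatives without stress-led clusters, with unnamed clusters given their first class and with library size alone were chosen after the data were seen, and the other alternatives were planned. Of 168 results for named genes, 143 kept their direction and their side of the threshold under all alternatives that gave a value. Over all alternatives, 75 of 2852 values for named genes no longer passed and 1 reversed. The reversed value was CD74 in fibroblast-like against basal-like cells, at 0.186 (log2) with no doublets removed, and the cause was not tested. Of the 39 called list results, 27 kept their call under all alternatives but the estimated correlation, which ended 27 calls and left 12. Over all alternatives, 65 of 1291 list values lost a call and 47 gained one. For the 11 drug targets and receptors with counts, the level in the highest class moved by less than 1 SD between specimens in 44 of 44 values under 4 alternatives that kept all replicates. That SD was near or above the mean for some of them, such as CHRM2 (1.22 ± 2.11 CPM) and CHRM3 (5.81 ± 5.05). For these the bound was too wide to show that a level was stable.

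The number of genes that differed moved by over 1.5 times under 3 other settings besides those with fewer specimens. Without the specimen term the counts were 1448 for club-like against luminal-like, 1076 for hillock-like against club-like and 1220 for fibroblast-like against mural-like cells. With a mitochondrial limit of 20% the hillock-like against club-like count was 1261 and the hillock-like share 1.48%. With minimums of 200 genes and 500 UMIs the club-like against luminal-like count was 1509. The cause of these changes was not tested. Without the stress-led clusters, which among the named classes held basal-like and luminal-like cells only, the calls of all 72 list results were the same.

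Leaving out each replicate in turn gave ranges of 2918 to 4713 for luminal-like against basal-like, 1199 to 2452 for club-like against luminal-like, and 669 to 1874 for hillock-like against club-like cells. The ranges were 657 to 1475 for fibroblast-like against mural-like, 2420 to 4014 for fibroblast-like against basal-like, and 1902 to 2888 for myeloid-like against T/NK-like cells. The lowest count came without replicate 3 in every comparison but club-like against luminal-like, where it came without replicate 2 and the count without replicate 3 was 1228. Without replicate 2 the hillock-like against club-like count was 1097. Fewer specimens lower the counts by themselves.

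The balance of higher and lower genes depended on the scaling. In luminal-like against basal-like cells, 47.9% of the differing genes were higher, against 58.6% with RLE size factors and 69.4% with library size alone, and in fibroblast-like against basal-like cells 46.9%, 59.8% and 69.4%. In fibroblast-like against mural-like cells the share was 47.1% and 68.9% with library size alone. Depth limited the drug targets: a count of 0 allows up to 2.06 CPM in mast-like cells and 0.064 CPM in basal-like cells.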

Other observations

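The following list genes were chosen after their values were seen, for classes that entered no comparison, and no test was run on them. In blood endothelial-like cells, the basement membrane proteoglycan HSPG2 averaged 203 ± 59.1 CPM (SD, n = 3), against 12.8 ± 3.46 in basal-like cells, the next class. AKR1C3, a steroid-reducing enzyme, averaged 195 ± 87.3 CPM there, against 27.2 ± 11.4 in hillock-like cells, and COL15A1 264 ± 23.4, against 81.3 ± 41.6 in fibroblast-like cells. HLA-E averaged 1550 ± 330 CPM in blood endothelial-like and 715 ± 163 in T/NK-like cells. In mast-like cells, DHRS9 averaged 103 ± 35.9 CPM, against 25.4 ± 15.2 in B/plasma-like cells. HPGD, which inactivates prostaglandins, averaged 402 ± 255 CPM in mast-like and 99.6 ± 62.4 in hillock-like cells, and ANXA1 5960 ± 896 and 2200 ± 1230.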
